A study of Mus musculus with 11 samples.

How the data were processed

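The series measured gene expression by RNA sequencing in the hippocampus of mice whose mothers had received particulate matter (PM) or normal saline (vehicle) by the nose during pregnancy. Per the labels, mothers were dosed 3 times, at gestational days 9, 12 and finally 15, gave birth at day 21, and the offspring were sampled when 14 to 18 weeks old. The PM dose was 200 µg per kg. There were 11 libraries, 5 of vehicle and 6 of PM, in 2 sets of deposit. The first set held replicates 1 to 3 of each group, and the second set held vehicle replicates 4 and 5 and PM replicates 4 to 6. The library numbers in the labels restart in the second set, and a treatment protocol is given only for that set. The set was therefore used as a covariate. The labels do not say whether the libraries came from separate animals or litters, so the p-values measure the spread between these samples, which may be technical in part.

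The deposited files hold 1 count per gene symbol and library, not normalized. Per the submitters' processing notes, the tools named were FastQC 0.11.9, Trimmomatic 0.36, STAR without a version, SAMtools 1.9, Picard 2.9.2 and HTSeq 0.9.1, and the genome builds named were mm10 and hg19. Values here are for mouse genes. Which strand setting was used for counting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies, such as histone and ribosomal protein genes with their pseudogenes, are uncertain. Per the labels' protocols, ribosomal RNA was removed from total RNA before library preparation with an NEBNext Ultra II kit and paired-end sequencing on a NovaSeq instrument. The labels' molecule field instead names polyA RNA. How the RNA was selected is therefore given in 2 ways.

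The files also carry the HTSeq summary counts. They stayed out of library sizes and tests. Counts with no feature, meaning not assigned to any annotated exon, made up 60.9% to 62.0% of all counts in vehicle libraries and 18.8% to 34.0% in PM libraries. With a strand setting, reads over exons on the opposite strand would also fall here, so these counts need not lie outside exons. Counts assigned to genes were 6012116 to 12496650 per vehicle library and 10938520 to 17763890 per PM library. A count of 0 in 1 library allows up to 3 counts, which is 0.499 CPM (counts scaled to a common library size) in the shallowest library and 0.169 CPM in the deepest. Such floors cover counting error only. No per-sample column was left unused. To look for libraries deposited 2 times, pairs of the same group were compared over genes with 20 or more counts. The lowest chi-square per degree of freedom, 2.01, was that of vehicle replicates 1 and 3, against 12.6 and 12.9 for the other vehicle pairs of that set. No pair was within sampling noise, so none was merged. This does not show that libraries come from separate animals.

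Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 14982 genes, and libraries were scaled by TMM. The robust quasi-likelihood test compared PM with vehicle with the set as covariate, two-sided, with Benjamini-Hochberg adjustment over all tested genes and an adjusted p threshold of 0.05. The PM effect in each set and its difference between sets came from 1 joint fit of the 4 combinations of group and set. Standard errors (SE) of log2 fold changes were taken as the size of the change divided by the square root of F. CPM values are given as mean ± SD on TMM-scaled library sizes.

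Before the data were examined, 50 gene lists were fixed, covering glutamate and other neurotransmitter receptors, synaptic genes, cell type markers of the hippocampus and its neighbours, stress and immune responses, and structural RNAs. Of these, 49 had at least 3 tested members and were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01. The named genes followed a rule fixed at the same time. It took the 15 largest rises and the 15 largest falls among genes past the threshold with a mean of at least 1 CPM and the same sign in both sets, all 7 NMDA receptor subunits, up to 4 members of smallest p of each list described, and Xist and Y-linked genes per library. Which lists were described with named members was settled after the data were seen. Gene positions and transcript lengths came from GENCODE mouse release M21 on GRCm38, the same assembly as mm10, to which 98.4% of the 24421 symbols in the files were matched.

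The steps were tested on simulated counts drawn from the means of the vehicle libraries, with the real library sizes and spread. With all libraries, 72.7% of genes changed 1.5-fold and 94.0% of genes changed 2-fold were recovered among 14795 genes, with 6 false calls. In the first set the shares were 56.6% and 84.0%, and in the second set 28.3% and 70.0%. For the difference between sets they were 12.0% and 62.0% among 14784 genes. At each fold only 99 or 100 genes were changed, up and down alike, and the groups did not differ otherwise in composition. These shares and false calls thus do not carry over to the real comparison, where 69.1% of genes were called. A simulated list that was raised ranked 1 of 49 and was the 1 list called. Simulated genes were drawn independently, whereas the estimated correlation in the real data reached 0.837 for ribosomal protein genes. The list check therefore cannot show how many lists of correlated genes are called falsely. An offset removes each library's trend with transcript length and GC content. It was checked on 1 simulated trend, a straight line in log transcript length put on PM libraries, over 14982 genes, and took the calls from 7871 to 0. The offset can follow such a line by its form, and no GC trend or other shape was simulated, so those were not checked.

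Alternatives covered other scalings (DESeq2 1.42.0 size factors, library totals, upper quartile), other count filters, a DESeq2 Wald test, limma voom with quality weights, fits without the set term, with replicate numbers as a block, with 1 surrogate variable (sva 3.50.0) or with Xist as covariate, estimated correlation and fry for lists, and each library left out in turn. After the data were seen, 5 more were added: the length and GC offset, protein-coding genes alone, the second set alone, the 7 libraries with Y-linked counts, and the fit without the 3 libraries highest in Ttr. The mitochondrially encoded genes of 1 list had 0 members in the files and were not analysed here.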

Results

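Hippocampal RNA of mice exposed before birth to PM was compared with that of vehicle controls in 11 libraries, 5 of vehicle and 6 of PM. Gene counts were 9992200 ± 2538400 per vehicle library (SD, n = 5) and 14443000 ± 2762400 per PM library (SD, n = 6). The libraries differed between groups in composition before any gene was tested. Counts with no feature were 61.4% ± 0.46 of all counts in vehicle libraries (SD, n = 5) and 26.0% ± 6.46 in PM libraries (SD, n = 6), with no overlap (two-sided exact permutation test over 462 splits, p = 0.0021645, the smallest these splits allow, adjusted p = 0.0037879 over 7 library measures). In the first set the means were 61.3% and 20.4%, and in the second set 61.5% and 31.7%, where the smallest p that 3 against 3 or 2 against 3 libraries can give is 0.1. Malat1, a nuclear non-coding RNA, took 2.19% ± 0.081 of gene counts in vehicle and 0.439% ± 0.361 in PM libraries. Rn45s, the ribosomal RNA precursor, took 1.57% ± 0.710 in vehicle and 9.97% ± 5.22 in PM libraries, and was higher in PM in both sets, with 14.4% against 1.25% in the first and 5.60% against 2.04% in the second.

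**Figure D1:**
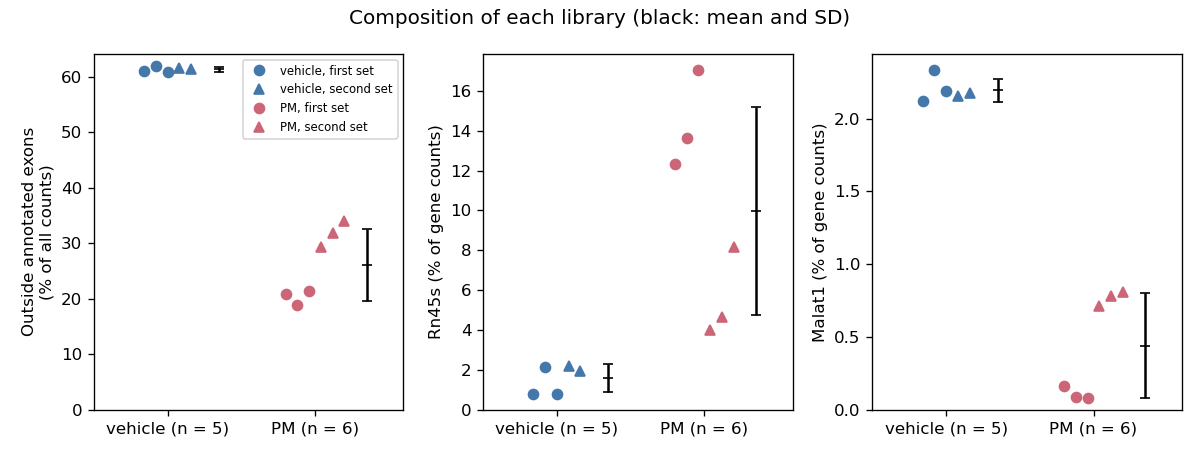
Share of all counts with no feature (labelled as outside annotated exons), and shares of gene counts on Rn45s and Malat1, in percent, for each vehicle and PM library. Circles are libraries of the first set, triangles those of the second, and black marks give the mean and SD. Every vehicle library lies above 60.8% with no feature and every PM library below 34.1%.

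The series title names NMDA receptors in the hippocampus of the offspring as its subject, and their 7 subunits were measured in every library. Grin2a and Grin2b, the glutamate-binding GluN2A and GluN2B subunits, were the most reduced in PM. Grin2a fell from 221.8 ± 9.38 CPM (SD, n = 5) to 20.2 ± 5.97 CPM (SD, n = 6), a 10.9-fold decrease (log2 fold change -3.44, SE 0.17, edgeR adjusted p = 3.392e-09). Grin2b fell from 966 ± 52.2 to 149 ± 40.7 CPM, a 6.71-fold decrease (log2 fold change -2.75, SE 0.16, edgeR adjusted p = 1.036e-08). Grin3a fell 2.63-fold, from 81.7 ± 6.63 to 30.9 ± 9.17 CPM (log2 fold change -1.39, SE 0.17, edgeR adjusted p = 6.077e-06). For these 3 genes all 6 PM libraries lay below all 5 vehicle libraries. With the length and GC trend removed the log2 fold changes were smaller, -1.89 for Grin2a (SE 0.12), -0.86 for Grin2b (SE 0.094) and -0.58 for Grin3a (SE 0.15), and still past the threshold. Grin2c rose from 35.9 ± 1.81 to 66.2 ± 16.9 CPM, with all 6 PM libraries above all 5 vehicle libraries (log2 fold change 0.81, SE 0.13, edgeR adjusted p = 0.0001101).

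Grin1, the obligatory GluN1 subunit, was 373 ± 29.9 CPM in vehicle and 259 ± 89.5 CPM in PM libraries (log2 fold change -0.64, SE 0.19, edgeR adjusted p = 0.008034). Its change lay in the first set, at -1.10 (SE 0.14), against -0.04 (SE 0.16, adjusted p = 0.8284) in the second, and the difference between sets passed the test (adjusted p = 0.001978). Fitted on the second set alone, Grin1 gave -0.03 (adjusted p = 0.73952), and with the length and GC trend removed -0.98 over all libraries (SE 0.13, adjusted p = 1.77e-05). Grin2d had a log2 fold change of 0.01 (SE 0.13, adjusted p = 0.9562), whose sign changed with the scaling, and Grin3b, at 2.14 ± 0.418 CPM in vehicle, one of -0.71 (SE 0.32, adjusted p = 0.06524). With the trend removed Grin3b was past the threshold at -1.23 (SE 0.28, adjusted p = 0.0019), and by set it was -1.34 in the first and 0.13 in the second (adjusted p = 0.04036 for the difference). Of the 7 subunits, 1 rose, 4 fell and 2 did not pass, and the counts adjusted over the list alone were the same, 1 and 4. As a list the subunits had a median log2 fold change of -0.71. No difference from other genes was detected (camera adjusted p = 0.24, and adjusted p = 0.762 with an estimated correlation). The median was -1.19 in the first set and -0.04 in the second. Beside these changes stands the composition of the libraries, with 26.0% of counts having no feature in PM against 61.4% in vehicle. Grin2a lies on chromosome 16 (9567898 to 9995560, GRCm38, minus strand) with an annotated transcript of 14634 bases. Grin2b lies on chromosome 6 (135713233 to 136173511) with one of 24060 bases, both above the median of 6760 bases in the longest of 5 length groups of genes.

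**Figure D2:**
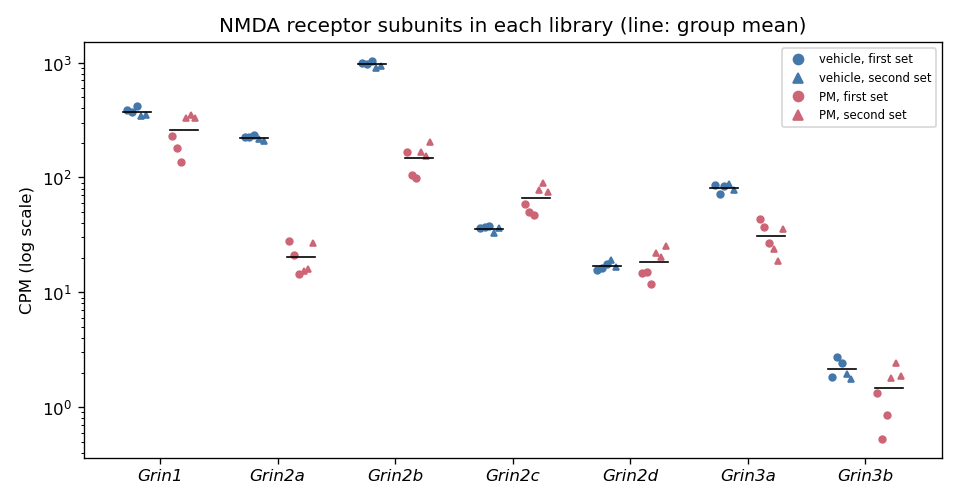
CPM of the 7 NMDA receptor subunit genes in each library, on a log scale, with vehicle in blue and PM in red, circles for the first set, triangles for the second and a line at each group mean. Grin2a, Grin2b and Grin3a are lower in all 6 PM libraries, while Grin1 in PM libraries of the second set lies at 327 to 349 CPM beside 340 and 351 CPM in vehicle.

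Across the transcriptome, 4904 genes were higher and 5450 lower in PM than in vehicle, 69.1% of 14982 tested genes, and 1739 rose and 2565 fell by more than 2-fold. Small structural RNAs and histone genes led the falls. Rpph1, the RNA of ribonuclease P, fell from 1638 ± 359 to 13.1 ± 15.4 CPM (log2 fold change -7.98, SE 0.72, edgeR adjusted p = 2.949e-06). Rmrp, the RNA of ribonuclease MRP, fell from 716 ± 105 to 8.17 ± 9.16 CPM (log2 fold change -7.38, SE 0.75). Scarna13, a small Cajal body RNA, fell from 65.1 ± 8.00 to 0.325 ± 0.316 CPM, and Hist1h4d from 62.5 ± 6.42 to 0.463 ± 0.296 CPM. Hist1h1e fell 57.5-fold and Hist1h1d 59.6-fold. Hist1h2ak had 1 count in the PM libraries together against 166 in vehicle, Hist1h3f 2 against 238, and Hist1h1a 3 against 231. The remaining genes among the 15 largest falls were Gm15881, 4930563F08Rik, 1700024B18Rik, 1700012D16Rik, Gm5643 and Speer4a. Of these, 4930563F08Rik lies opposite Auts2 and 1700024B18Rik opposite Fgf14, while 1700012D16Rik lies within St6galnac3 and Gm15881 within Galntl6. The list of non-polyadenylated and structural RNAs had 3 members higher, 6 lower and 1 not passed of 10 (3 and 6 adjusted over the list alone). Its members moved both ways, Snord17 to -4.35 and Rn45s to 2.58, and the list did not pass (camera adjusted p = 0.192).

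The largest rises were those of Lars2 and Mir6236. Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366927 to 123462666, plus strand), rose from 29.2 ± 26.6 to 5711 ± 2180 CPM (log2 fold change 7.73, SE 0.66, edgeR adjusted p = 1.884e-06). Mir6236 rose from 26.2 ± 43.3 to 626 ± 377 CPM (log2 fold change 5.45, SE 1.56, edgeR adjusted p = 0.01218), but on the second set alone its adjusted p was 0.062186. Gh, growth hormone, reached 4.23 ± 2.71 CPM in PM from 6 counts in the vehicle libraries together. It did not pass on the second set alone (adjusted p = 0.19878). Psmb8, an immunoproteasome subunit, rose 6.72-fold, Fabp5, a fatty acid binding protein, 7.23-fold, Ccs, the copper chaperone of superoxide dismutase, 7.54-fold, Nme2, a nucleoside diphosphate kinase, 6.32-fold, Fam213b 11.7-fold and Mir703 9.99-fold. The other 6 were genes of ribosomal proteins and the ATP synthase.

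Ribosomal protein genes rose together, with 28 of 29 tested members higher, 0 lower and 1 not passed (28 adjusted over the list alone) and a median log2 fold change of 1.80 (camera adjusted p = 2.47e-11, and adjusted p = 0.762 with an estimated correlation). Of the list, Rps14 rose 11.9-fold, from 34.6 ± 4.94 to 411 ± 134 CPM, Rpl13 5.74-fold, Rplp0 3.74-fold and Rpl3 by a log2 fold change of 2.26. Ribosomal protein genes outside the list, named for their large rise, were Rps27a (7.72-fold), Rpl9 (7.37-fold) and Rpl36 (6.61-fold). Nuclear genes of the respiratory chain also rose, 22 of 23 higher and 1 not passed (22 adjusted over the list alone), with a median of 1.08 (camera adjusted p = 5.91e-08, and adjusted p = 0.762 with an estimated correlation). Among them, Atp5e rose 6.33-fold, Ndufv1 3.30-fold, Cox4i1 3.19-fold and Sdhb 2.76-fold. Transcript lengths of the named members of the lists run from 421 bases for Atp5e to 1661 for Ndufv1. Outside the lists, Rpl36 has 383 bases and Rpl9 2690. With the length and GC trend removed the medians of the ribosomal protein and respiratory chain lists were 1.28 (adjusted p = 2.73e-11) and 0.80 (adjusted p = 8.71e-08).

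Fold changes fell with transcript length over 14853 genes (Spearman rho -0.495 across genes, which are not independent replicates) and rose with GC content (rho 0.394). Of 5 equal groups of genes by length, the one with the shortest transcripts, of median 1270 bases, had a median log2 fold change of 0.63 and 59.7% of its genes higher. The one with the longest, of median 6760 bases, had a median of -0.86 and 75.7% of its genes lower. Within the first set rho with length was -0.468 and within the second -0.462. Between the 2 sets of vehicle libraries it was 0.0209. For GC content rho was 0.255 in the first set and 0.53 in the second, -0.203 between the sets of vehicle libraries and 0.361 between those of PM libraries.

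**Figure D3:**
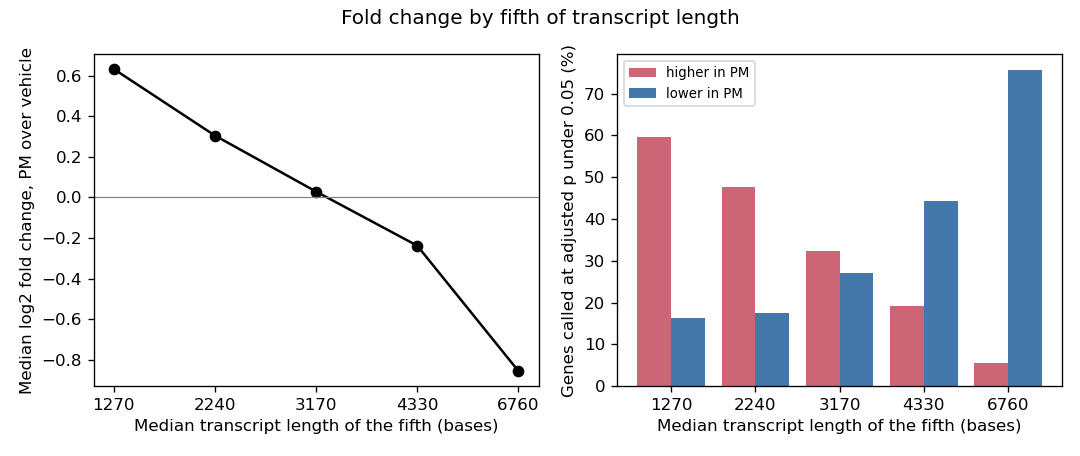
Median log2 fold change of PM over vehicle (left) and percent of genes called higher or lower (right) in 5 equal groups of genes by transcript length in bases, labelled by the median length of each. The median is 0.63 in the shortest and -0.86 in the longest.

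Metabotropic glutamate receptors had 6 of 7 members lower and 1 not passed (6 adjusted over the list alone), with a median of -1.34 (camera adjusted p = 0.0291, and adjusted p = 0.762 with an estimated correlation). Grm5 fell from 637 ± 25.3 to 235 ± 45.0 CPM, Grm7 fell 2.61-fold and Grm3 2.53-fold. Dopamine, serotonin and acetylcholine receptors had 12 of 17 lower and 5 not passed (12 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 0.0108, and adjusted p = 0.762 with an estimated correlation). Chrm2, a muscarinic receptor, fell 11.4-fold, Htr2a, a serotonin receptor, 6.50-fold, Chrna7, the alpha7 nicotinic receptor, 4.28-fold and Chrm3 2.06-fold. Kainate receptor subunits had 5 of 7 lower and 2 not passed (6 lower adjusted over the list alone), among them Neto1, which fell 4.01-fold, Grik2 (2.91-fold), Neto2 (2.22-fold) and Grik1 (2.20-fold). That list missed the threshold (camera adjusted p = 0.0771). With the length and GC trend removed, Grik2 was no longer past it (log2 fold change -0.15, adjusted p = 0.13953).

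AMPA and GABA-A receptor genes moved both ways. Of 11 AMPA receptor and auxiliary subunits, 4 were higher, 5 lower and 2 not passed, with the same 4 and 5 adjusted over the list alone (camera adjusted p = 0.582). Shisa9 fell 2.28-fold, Gria4 1.84-fold and Gria3 1.67-fold, while Cnih2 rose 1.97-fold. With the length and GC trend removed, Gria4 (-0.23), Gria3 (-0.11) and Cnih2 (0.02) were no longer past the threshold. Of 12 GABA-A subunits, 2 were higher, 7 lower and 3 not passed, also 2 and 7 adjusted over the list alone (camera adjusted p = 0.24). Gabrg3 fell 13.0-fold and Gabrb1 2.61-fold, and Gabrd, a subunit of extrasynaptic receptors, rose 3.93-fold. Gabrb1 turned to 0.24 (adjusted p = 0.065416) with the length and GC trend removed. Postsynaptic density and NMDA receptor signalling genes had 7 of 26 higher, 17 lower and 2 not passed, also 7 and 17 adjusted over the list alone (camera adjusted p = 0.208). Dlgap2 had a log2 fold change of -1.93, Dlg2, the scaffold PSD-93, fell 2.49-fold and the kinase gene Camk4 2.06-fold, while Dlg4, the scaffold PSD-95, rose 1.98-fold from 570.5 ± 35.05 to 1131 ± 66.5 CPM.

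All 24 autism and intellectual disability risk genes of the list fixed beforehand were lower in PM (24 adjusted over the list alone), with a median log2 fold change of -1.05 (camera adjusted p = 1.98e-07, and adjusted p = 0.762 with an estimated correlation). Ube3a, a ubiquitin ligase gene, fell 5.21-fold and Cntnap2 2.54-fold. With the length and GC trend removed the median was -0.22 and the list no longer passed (adjusted p = 0.239). Cntnap2 then stood at -0.10, not past the threshold.

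Microglia markers and interferon response genes were higher in PM as lists, though not every member was. Of 15 microglia markers, 11 were higher, 1 lower and 3 not passed, also 11 and 1 adjusted over the list alone (median 0.84, camera adjusted p = 0.00439, and adjusted p = 0.762 with an estimated correlation). C1qa rose from 11.7 ± 1.23 to 50.7 ± 7.44 CPM, Aif1 4.09-fold, C1qb 3.00-fold and C1qc 2.51-fold. Of 20 interferon response genes, 11 were higher, 1 lower and 8 not passed, also 11 and 1 adjusted over the list alone (median 0.72, camera adjusted p = 0.0287, and adjusted p = 0.762 with an estimated correlation). Bst2 rose 5.00-fold, H2-K1, a class I histocompatibility gene, 4.11-fold and Ifi27 3.55-fold, beside Psmb8. Beside these lists, 7 of 12 endothelial markers and 6 of 10 pericyte and smooth muscle markers were higher, in lists that did not pass, and counts with no feature were 26.0% in PM against 61.4% in vehicle libraries.

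Astrocyte, myelin and oxidative stress lists did not pass as lists, but with the length and GC trend removed the astrocyte list did (median 0.41, adjusted p = 0.0353). Without that removal the astrocyte list had adjusted p = 0.762 with an estimated correlation, which was not run with the trend removed. Of 12 astrocyte markers, 6 were higher, 4 lower and 2 not passed (6 and 4 adjusted over the list alone, camera adjusted p = 0.339), with S100b up 3.64-fold, Aldh1l1 2.50-fold, Aldoc 2.41-fold and Fgfr3 1.83-fold. Of 15 myelin and oligodendrocyte genes, 7 were higher, 2 lower and 6 not passed (7 and 2 adjusted over the list alone, camera adjusted p = 0.291). Mobp rose 2.19-fold, Cnp 1.87-fold, Trf 1.84-fold and Mag 1.81-fold, but Cnp and Mag did not pass with the length and GC trend removed (adjusted p = 0.11564 and 0.10506). Of 19 NRF2 and oxidative stress genes, 10 were higher, 5 lower and 4 not passed (11 and 5 adjusted over the list alone, camera adjusted p = 0.186). Gpx4, which reduces lipid peroxides, rose 4.03-fold, Sod1 2.64-fold, Keap1 2.40-fold and Gsta4 2.02-fold.

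The list of targets of the aryl hydrocarbon receptor, which binds polycyclic aromatic compounds, also holds Ahr, the gene of the receptor itself. Of its 9 genes only 5 were kept by the count filter and tested. Of the 5, 1 was higher, 3 lower and 1 not passed (1 and 3 adjusted over the list alone, camera adjusted p = 0.608). Ahr fell 2.59-fold and Tiparp 1.49-fold, and Nqo1 rose 1.92-fold. Cyp1b1 had a log2 fold change of -0.59 (SE 0.24, adjusted p = 0.04398) and was not past the threshold with DESeq2 size factors (adjusted p = 0.060356). Tiparp and Nqo1 were not past it with the length and GC trend removed (adjusted p = 0.40284 and 0.057032). Of 11 inflammatory cytokine and NF-kB target genes, 5 were higher, 3 lower and 3 not passed, also 5 and 3 adjusted over the list alone (camera adjusted p = 0.608). Nfkbia rose 2.14-fold, Myd88 1.99-fold and Il18 1.61-fold, while Ptgs2, the inducible cyclooxygenase, fell 2.06-fold.

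**Figure D4:**
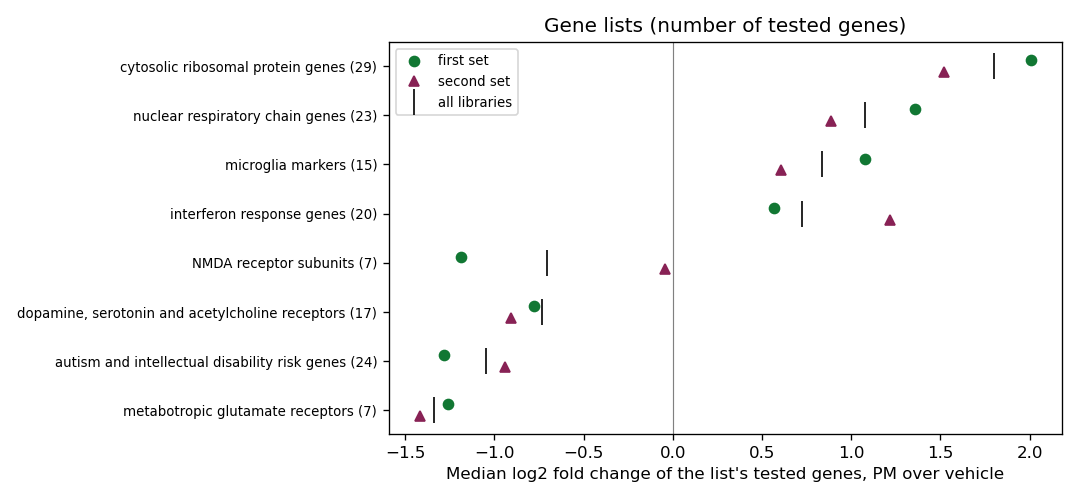
Median log2 fold change of PM over vehicle of the 7 lists past the camera threshold and of the NMDA receptor subunits, with the number of tested genes in brackets. Black marks are all libraries, circles the first set and triangles the second. The NMDA receptor subunits lie at -1.19 in the first set and -0.04 in the second.

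The PM effect was also tested within each set. In the first set 4809 genes were higher and 5835 lower, and in the second 4844 and 4862. Of these, 3458 were higher and 3920 lower in both sets, against 1555 and 1894 for independent lists, and 511 were called in opposite directions. Fold changes of the sets correlated across genes (Pearson r 0.772, Spearman rho 0.757), genes not being independent replicates. Vehicle and PM libraries differed in composition in both sets, so neither the overlap nor the correlation can be put down to exposure. Grin2a was lowered alike, by -3.42 and -3.47, and no difference between sets was detected (adjusted p = 0.9317). The effect of 4428 genes differed between the sets, 2618 with a higher and 1810 with a lower value in the second. Without vehicle replicate 5 this count was 2400. Vehicle libraries of the first set all carried Y-linked counts, and those of the second had high Xist without them. Set and sex-linked composition thus cannot be told apart in vehicle libraries. PM libraries of the first and second set differed in composition, with means of 20.35% and 31.7% of counts having no feature. Rn45s took 14.35% and 5.60% of their gene counts, and Malat1 0.112% and 0.766%. In vehicle libraries the means with no feature were 61.3% and 61.5%. The count of 4428 was adjusted for none of these. Rmrp changed by -9.53 in the first set and -5.60 in the second (difference 3.92, adjusted p = 0.001385), and Lars2 by 8.93 and 6.37 (difference -2.56, adjusted p = 0.01545). Between the sets of PM libraries 7146 genes differed by edgeR and 7280 by DESeq2. Between the sets of vehicle libraries edgeR called 0 genes, with 535 at an unadjusted p under 0.05, DESeq2 called 0, and edgeR on the vehicle libraries alone called 6. The counts of 0 do not show that these sets were alike. They missed Xist, at 1.76 to 3.17 CPM in vehicle replicates 1 to 3 against 2465 and 2279 CPM in replicates 4 and 5.

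**Figure D5:**
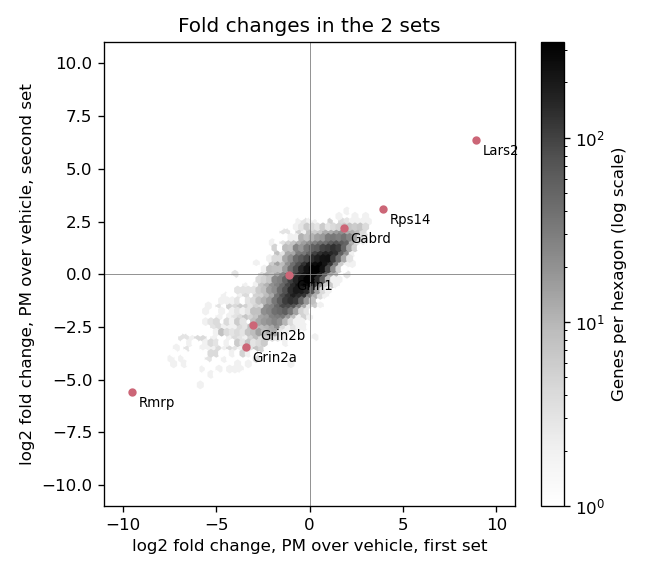
Log2 fold change of PM over vehicle in the first set (horizontal) and the second set (vertical) for 14982 genes, shaded by the number of genes per hexagon on a log scale, with 7 genes marked in red. Most genes lie along the diagonal, and Grin1 lies at -1.10 and -0.04.

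Xist, expressed from the inactive X chromosome of females, was at 2465 and 2279 CPM in vehicle replicates 4 and 5, at 187.1 CPM in PM replicate 3 and at 949.1 CPM in PM replicate 6. In those 4 libraries the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had at most 1 count each. The other 7 libraries carried Y-linked counts, with Ddx3y between 49.1 and 67.7 CPM and Xist between 0.338 and 15.96 CPM. High Xist without Y-linked counts was thus seen in 2 of 5 vehicle libraries, both in the second set, and in 2 of 6 PM libraries. Choroid plexus markers varied between libraries. Ttr, which encodes the choroid plexus product transthyretin, was at 1099 CPM in PM replicate 1, 2171 CPM in PM replicate 3 and 1071 CPM in vehicle replicate 5, and between 14.3 and 237 CPM in the other 8. The median of choroid plexus markers was 0.84 in the first set and -3.50 in the second. Of 13 choroid plexus markers, 0 were higher, 1 lower and 12 not passed (0 adjusted over the list alone, camera adjusted p = 0.617). Kl had a log2 fold change of -1.39 (SE 0.40, adjusted p = 0.008582), Kcnj13 of -1.61 (SE 1.02), Otx2 of -1.09 (SE 0.70) and Clic6 of -1.04 (SE 0.80). By set these were 0.21 and -4.39 for Kcnj13, 0.24 and -2.96 for Otx2, and 0.43 and -3.08 for Clic6. For these genes no difference between sets passed (adjusted p = 0.08187, 0.0738 and 0.08958), but it did for 2 of the 13 markers. Kl was no longer past the threshold with the length and GC trend removed.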

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

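The tests of the broad split, of histone and intronic genes, of the first set's splits, of the ambiguous share, of matched genes, of the length trend on NMDA receptor genes and of the confounded explanations were chosen after the results were seen, and the pass mark for the ribosomal word search was set aside afterwards, as told below. Splits of the 11 libraries into 5 and 6, 100 in number with the real one, gave as many changed genes in 1, the real split. That is the smallest share these splits allow. A chance division of these libraries is thus an unlikely source of the count of 10354, provided that the libraries are independent. The labels do not say whether they came from separate animals or litters, so chance at that level is not excluded. The highest other split gave 8512, and the splits with 8011 and 8512 set 5 PM libraries against the 5 vehicle libraries and 1 PM library. For the 7 lists past the threshold chance cannot be excluded, as 67 of the 100 splits gave as many and the highest other gave 19. For the NMDA receptor list median of -0.71 it cannot be excluded either, as 5 of the 100 splits, the real one and 4 others, gave a median as far from 0 and the highest other was 1.15 from 0. Of the 4, 1 is the split with 8011 genes. The 10 splits of the 6 first-set libraries are too few for a share under 0.05, with 10644 genes in the real split, the 1 that reached it, and 0 in the highest other.

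The first pattern is the change of 69.1% of tested genes beside libraries of different composition. Counting vehicle libraries alone with a strand setting is argued against by genes overlapped on the opposite strand, which differed from others by 0.032 (bootstrap -0.053 to 0.145), while ambiguous counts leave it open, in PM 1.22 times those in vehicle as a share of gene and ambiguous counts but 2.35 times as a share of all counts. A difference in RNA selection may account for part, as replication-dependent histone genes, which lack poly(A) tails, had a median 5.19 below that of polyadenylated histone genes (difference -5.19, and -5.25 and -5.06 in the sets). More unspliced RNA in vehicle libraries may also account for part, as non-coding genes inside introns had a median lower than those outside other genes (difference -3.23, permutation p = 1e-05, the smallest possible). An effect of prenatal exposure cannot be told apart from these, because the lowest vehicle share with no feature lies 26.9 percentage points above the highest PM share, so no libraries of like composition can be compared.

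The second pattern is the fall of Grin2a, Grin2b and Grin3a. The fitted trend with transcript length and GC content did not take up the whole fall. With it removed the 3 genes stood at -1.89, -0.86 and -0.58 (SE 0.12, 0.094 and 0.15). Whether such a trend is the whole cause cannot be decided from this, because 9498 of 14982 genes were still called with it removed. These SE cover the spread between libraries, not that of single genes around the trend. Whether genes alike in length, GC content, span and level fall as far stays open: the mean of the 3 (-2.53) lay at percentile 0.31 of the 3 lowest in 10000 draws of 1 matched gene per subunit, and at 0.16 in an earlier test that did not allow for picking 3 of 7, but matched genes were shorter, at a median of 10600 bases for Grin2a and 11700 for Grin2b. Alone, Grin2a lay at percentile 1.5, Grin2b at 2 and Grin3a, whose matched genes were of like length, at 26.5, so its fall was not unusual among them. Selection of RNA and prenatal exposure cannot be told apart here, because of the gap of 26.9 percentage points.

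The last pattern is the rise of Lars2 and Mir6236 beside Rn45s. The explanation of ribosomal RNA reads assigned to this gene could account for each, and this cannot be told apart from a rise of the genes. Of the 25-base words of Lars2, 0 of 11142 occurred in annotated ribosomal RNA, and of those of Mir6236, 0 of 99. The bound written before the search, 0 words, was met and would have counted against this explanation, but it was set aside after the result was seen, because the search covered annotated parts of 7100 nuclear and 2537 mitochondrial bases and left out 616 bases between them and the rest of the precursor. No biological explanation was tested.

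Library measures and named genes were examined within the vehicle and within the PM libraries, 220 groups in all. In 9 groups, all of named genes, 1 library lay far from the others, where chance gives about 1 in 20. They were Gh in vehicle replicate 1 (0.396 CPM), Fam213b and Atp5e in vehicle replicate 4 (5.23 and 12.9 CPM), Hist1h2ak in PM replicate 3 (0.0716 CPM), 4930563F08Rik in PM replicate 4 (0.445 CPM), 1700012D16Rik in PM replicate 5 (0.218 CPM), Il18 in PM replicate 1 (14.8 CPM), and Chrna7 and Chrm3 in vehicle replicate 3 (59.8 and 62.7 CPM).

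As described above, the vehicle libraries of the 2 sets also differed in sex-linked counts, and the PM libraries of the 2 sets in composition. The PM effect differed between the sets by an interaction test for 4428 genes, and for 2400 without vehicle replicate 5. Among them were 19 of the 103 named genes, with the effect in the second set minus that in the first in log2 units as follows. It was -2.56 for Lars2, -7.00 for Mir6236, -0.83 for Rps14, -1.15 for Rps27a, -0.75 for Rpl9, 3.34 for Rpph1, 2.10 for Scarna13, 3.92 for Rmrp and 4.22 for 4930563F08Rik. It was 1.06 for Grin1, 0.73 for Grin2c, 0.59 for Grin2d, 1.47 for Grin3b, -0.75 for Grm3, 0.66 for Dlgap2, -0.54 for S100b, -0.76 for Tiparp, -0.51 for Rpl3 and -0.39 for Ndufv1.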

How the results depend on the processing

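The length and GC offset, protein-coding genes alone, the second set alone, the 7 libraries with Y-linked counts and the fit without the 3 libraries highest in Ttr were chosen after the data were seen. Over all settings run, genes higher in PM numbered 4318 to 5557 and genes lower 4495 to 6140. With the offset 9498 genes were called, 7001 of them also without it and in the same direction, and with coding genes alone 9698. The DESeq2 Wald test, which also tested more genes (18923), had a median over all genes of -0.13, against -0.04. The replicate block gave 4318 higher and 4890 lower, 7 lists and an NMDA receptor median of -0.72, and 10269 and 8978 genes in the sets fitted alone. Replicate numbers shared by the groups correlated between -0.278 and 0.172, and no library matched its own number best. Lists past the threshold numbered 14 with no count filter, where more genes were tested, 9 with the offset, 0 with an estimated correlation and 43 with fry, which asks another question, whether the list changed at all. The NMDA receptor median of -0.71 passed with fry (adjusted p = 0.000114, against 0.083 to 0.762 in the other settings) and was -0.03 in the second set alone. Leaving out 1 library gave 4657 to 5096 higher, 5021 to 5435 lower, 7 to 8 lists, 9846 to 10641 genes in the first set, 7943 to 10020 in the second and an NMDA receptor median of -0.91 to -0.59. The difference between sets ranged from 2400 without vehicle replicate 5 to 5612 without PM replicate 1.

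For 103 named genes, 2798 of 2865 values kept their direction and side of the threshold, 37 lost and 17 gained the call, and 13 reversed. Grin2d, not past the threshold in any of them, reversed with library totals (-0.0099), a mean of at least 1 CPM (-0.0040), the block (-0.054), a surrogate variable (-0.0023), the Xist covariate (-0.028), the offset (-0.014) and the 7 libraries (-0.054), and ranged from -0.094 to 0.090 when 1 library was left out. Grin3b was 0.14 in the second set alone, Gabrb1 0.24 with the offset and Clic6 between -1.59 and 0.041, the latter without vehicle replicate 5. The cause of these was not tested. Floors of 0.169 to 0.499 CPM per library limit what counts of 0 exclude.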

Other observations

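Other lists fixed beforehand did not pass the list test, though with the length and GC trend removed, a setting chosen after the data were seen, endothelial (adjusted p = 0.0257) and interneuron markers (adjusted p = 0.0324) did. Both had adjusted p = 0.762 with an estimated correlation, run without that removal. Members of the lists moved as follows, given as higher, lower and not passed with the camera adjusted p, and with counts adjusted over the list alone only where they differ. Heat shock genes had 7, 0 and 6 (0.0771), endothelial markers 7, 0 and 5 (0.0937, 6 higher over the list alone), endoplasmic reticulum stress genes 8, 2 and 5 (0.186), and apoptosis genes 6, 1 and 9 (0.228). Pericyte and smooth muscle markers had 6, 2 and 2 (0.247), complement genes 4, 1 and 5 (0.247), activated microglia genes 3, 1 and 4 (0.247), and metal response genes 6, 3 and 1 (0.291). Reactive astrocyte genes had 2, 4 and 2 (0.606, 5 lower over the list alone), T cell, B cell and peripheral myeloid markers 0, 2 and 1 (0.571, 0 lower over the list alone), glucocorticoid response genes 3, 6 and 4 (0.669, 4 higher over the list alone), and circadian clock genes 5, 6 and 5 (0.885). DNA methylation and histone modifying enzymes had 3, 8 and 4 (0.235, 4 higher over the list alone).

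Among neuronal lists, interneuron markers had 2, 7 and 6 (0.401), CA1 pyramidal markers 2, 4 and 4 (0.472), CA2 and CA3 pyramidal markers 3, 3 and 6 (0.688, 1 lower over the list alone), dentate granule cell markers 3, 5 and 2 (0.511), and neurogenesis and immature neuron markers 4, 6 and 2 (0.523). Immediate early genes had 3, 7 and 7 (0.571), presynaptic vesicle and release genes 8, 10 and 6 (0.608), neurotrophins and their receptors 1, 2 and 4 (0.617), and oligodendrocyte precursor markers 1, 3 and 5 (0.608). Of the neighbouring tissues, thalamic and habenular genes had 3, 6 and 3 (0.429), cortical genes 4, 4 and 4 (0.606), striatal genes 2, 3 and 5 (0.885), hypothalamic and pituitary genes 2, 1 and 1 (0.571), meningeal and fibroblast markers 4, 3 and 5 (0.879), ependymal and cilia markers 0, 1 and 7 (0.95, 0 lower over the list alone) and erythrocyte genes 2, 1 and 0 (0.52). Sex-linked genes had 0, 2 and 7 (0.319).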
